A study of Mus musculus with 15 samples.

How the data were processed

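Liver RNA from 15 male mice was measured on GeneChip Mouse Gene 2.0 ST arrays, 1 array per mouse, with 6 RYGB (Roux-en-Y gastric bypass), 5 Sham AL (sham surgery, fed ad libitum) and 4 BWm (sham surgery, body weight matched to the RYGB mice) arrays, which the titles number as biological replicates. Per the series' design text, the authors processed the arrays together with the robust multi-array average in Affymetrix Expression Console 1.4.1.46. The deposited values are log2 signals of 41345 transcript clusters per array, without missing values. Per the same text, the authors called genes by a one-way analysis of variance at p under 0.05 with an absolute fold change of at least 1.5. Their lists of genes were not used here. The scanner files were not used here, so signal over background was not measured. The version of the probe annotation and the genome build behind it are not given in the sources used here, and no coordinates are reported.

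The probe table named 1 symbol for 23521 clusters, several symbols for 1814 and none for 16010. Clusters with several symbols or none were left out of the tests. Of the clusters with 1 symbol, 23328 were found by their Entrez number in the mouse RefSeq annotation, and 0 symbols needed updating. For the 1082 genes with more than 1 cluster, the cluster with the highest mean over all arrays was taken, which left 22180 genes. No filter on dim genes was applied. Members of families with near-identical copies (among them Cyp2c, Cyp3a, Cyp4a, Acot, Hamp and Serpina genes) can share probe signal, so their values can mix copies. Of 810 genes on the fixed lists, 728 were measured and 82 were not matched.

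The 3 comparisons (RYGB against Sham AL, RYGB against BWm, BWm against Sham AL) were contrasts in 1 limma fit (limma 3.58.1 in R 4.3.3; lmFit and eBayes with default settings) over all 15 arrays, with 12 residual and 5.85 prior degrees of freedom. Tests were two-sided, and adjusted p values are Benjamini-Hochberg values over all genes tested, with a threshold of 0.05. Errors after a fold change are standard errors (SE) from the moderated variance. Gene lists, 38 in all, covering liver pathways and the cell types that a piece of liver can hold, were tested with camera at a preset correlation between genes of 0.01 and adjusted over the lists of a comparison. The same lists were tested with a correlation estimated for each list and with fry. The directional test of fry asks whether the genes of a list move, on balance, one way, and it does not compare the list with other genes. Where a called list is described, the count adjusted over the list alone is given beside the count adjusted over all genes. Comparisons of per-array scores used exact two-sided permutation tests. Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9 were used for tables and figures.

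Before the data were examined, the comparisons, tests, gene lists, most alternatives and the rule for named genes were fixed. The rule took, in each comparison, the 8 largest rises and the 8 largest falls among genes past the threshold, the 3 members with the smallest p of every list past the camera threshold, and 20 fixed genes of bile acid, lipid and glucose metabolism, 15 of which were analysed; the others are not reported here. Predicted genes, olfactory and vomeronasal receptors and Mup genes were not among the largest changes. The rule gave 74, 96 and 82 genes in the order of the comparisons above. Examples from them are named. Genes outside the rule are said to have been chosen after their values were seen.

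The tests were tried on simulated data with the size of this design, with 200 of 22180 genes changed. In RYGB against Sham AL, 64.2% of genes changed 1.5-fold, 97% of those changed 2-fold and 100% of those changed 4-fold were called, with 10 false calls. For RYGB against BWm these were 53.7%, 94% and 100% with 14 false calls, and for BWm against Sham AL 50.7%, 95.5% and 100% with 12 false calls. In a further simulated draw, with a shifted cholesterol synthesis list as the only change, that list was called in every comparison. This held for camera with the preset correlation, camera with an estimated correlation and fry, and 0 of the other 37 lists were called. Genes were drawn independently of each other, so these draws cannot show how often lists are falsely called where their members vary together.

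Alternatives were a filter on level, quantile normalization, subtraction of array medians, the mean of a gene's clusters, all transcript clusters, fits on the compared groups only, trended and robust variance priors, array weights, a replicate block, a block for animal number, the methods' one-way ANOVA, and leaving out each array in turn. The labels give no scan date or other batch. Descriptions give an animal number whose meaning is not stated, with 3 RYGB, 1 Sham AL and 0 BWm animals numbered under 50 and the others above 60. The array of Sham AL replicate 4 carried transcripts of other tissues and was kept, since the design fixed all 15 arrays, and values without it are given for the lists whose camera call changed without it, and for some others.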

Results

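Gene expression was measured in the livers of 15 male mice that carry the human ApoE*3-Leiden and CETP genes, which give mice a more human-like lipoprotein profile. The mice ate a diet with 60% fat and 0.25% cholesterol for 6 weeks, had surgery, and were killed 20 days later. In 6 mice the surgery was Roux-en-Y gastric bypass (RYGB), in which food passes from a small stomach pouch directly into the jejunum. A sham operation was done in 5 mice fed ad libitum (Sham AL) and in 4 mice kept at the body weight of the bypass mice (BWm). Medians of the 15 arrays lay between 3.89 and 4.02 on the log2 scale, and Pearson's r across genes between any 2 arrays lay between 0.957 and 0.986. The number of arrays limits the precision. The median SE of a log2 fold change was 0.127 for RYGB against Sham AL, 0.135 for RYGB against BWm and 0.14 for BWm against Sham AL.

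The liver of Sham AL replicate 4 carried transcripts of adrenal gland and brown fat. Cyp11b1, an enzyme of steroid synthesis in the adrenal cortex, measured 10.37 on this array against 2.86 ± 0.32 (SD, n = 4) on the other Sham AL arrays. Ucp1, the uncoupling protein of brown fat, measured 11.89 against 3.87 ± 0.46 (SD, n = 4). On this array 662 genes lay over 1 log2 unit from the mean of the other arrays of the group, against 53 to 128 genes on each of the other 14 arrays. These genes were chosen after their values were seen, and values without this array are given for the gene lists whose camera call it ended or brought about, and for some others.

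**Figure D1:**
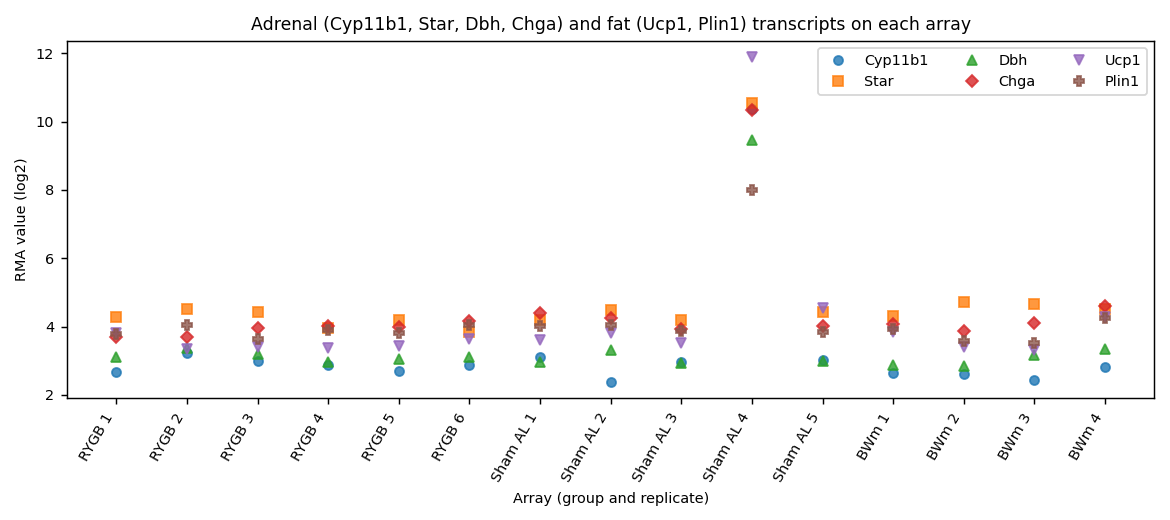
Log2 signal (y axis) of 4 adrenal genes (Cyp11b1, Star, Dbh, Chga) and 2 fat genes (Ucp1, Plin1) on each of the 15 arrays (x axis), 1 symbol per gene. Sham AL replicate 4 lies apart from every other array, with Ucp1 at 11.89 and Star at 10.56.

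The comparison of RYGB with Sham AL asks what bypass together with its weight loss changed in the liver. Targets of ATF4, the factor of the amino acid response (8 of 22 called), and cholesterol synthesis genes (6 of 20 called) were higher after bypass as lists, and lipid droplet markers (6 of 22 called) were lower. These were camera calls with the preset correlation, with adjusted p = 0.06, 0.2 and 0.14 with an estimated correlation. Slc7a11, the cystine transporter, rose 6.53-fold (log2 2.71 ± 0.35 SE, adjusted p = 0.00055), from 3.47 ± 0.4 (SD, n = 5) to 6.18 ± 0.97 (SD, n = 6). Its Sham AL mean lay under the lowest array median of 3.89, and without a measure of signal over background the exact fold is uncertain. S100g, a calcium-binding protein best known from the intestine, rose 5.93-fold (log2 2.57 ± 0.28 SE, adjusted p = 0.00033), and Sqle, which makes squalene epoxide on the way to cholesterol, rose 4.99-fold (log2 2.32 ± 0.4 SE, adjusted p = 0.0058). Scd1, the stearoyl-CoA desaturase, fell 2.23-fold (log2 -1.16 ± 0.14 SE, adjusted p = 0.00049). Hamp2, a relative of the iron hormone hepcidin, fell 9.49-fold (log2 -3.25 ± 0.42 SE, adjusted p = 0.00062).

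Among the stress lists, 8 of the 22 measured ATF4 targets, genes switched on when amino acids run short, rose and 0 fell (16 rose when adjusted over the list alone). Atf3 (log2 1.66 ± 0.24) and Trib3 (log2 1.49 ± 0.22) were among them. The camera adjusted p of the list was 1.2e-13, and it was adjusted p = 0.06 with an estimated correlation. Of 18 NRF2 targets, genes of the defence against oxidants, 7 rose and 0 fell (12 rose and 1 fell adjusted over the list alone), among them Cbr1 (log2 1.18 ± 0.2) and Osgin1 (log2 1 ± 0.17). The NRF2 list, which shares Slc7a11 with the ATF4 list, had a camera adjusted p of 6.2e-09 and adjusted p = 0.14 with an estimated correlation. By its mean per array, relative to all arrays, RYGB replicate 1 lay at -0.084, within the range of the Sham AL arrays (-0.27 to -0.016), and the other 5 RYGB arrays between 0.439 and 0.652. Of 20 ER folding genes, chaperones and helpers of the endoplasmic reticulum, 4 rose and 0 fell (12 rose adjusted over the list alone), led by Creld2 (log2 0.96 ± 0.15). The list's camera adjusted p was 5.6e-11, with adjusted p = 0.15 with an estimated correlation.

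Cholesterol synthesis genes that answer to SREBP2 rose in 6 of 20 cases and fell in 0 (11 rose adjusted over the list alone), with a list median of log2 0.63, and 0.67 without Sham AL replicate 4. Besides Sqle, Nsdhl rose by log2 1.35 ± 0.27. Camera gave an adjusted p of 4e-10 for this list, and adjusted p = 0.2 with an estimated correlation. By the list's mean, RYGB replicates 3 and 5 lay at -0.06 and 0.097, within and just above the range of the Sham AL arrays (-0.481 to 0.087), and the other 4 RYGB arrays between 0.344 and 0.89. Of 31 acute phase genes, plasma proteins and their regulators that respond to injury, 5 rose and 1 fell (15 and 3 adjusted over the list alone). The metallothioneins Mt1 (log2 1.31 ± 0.19) and Mt2 (log2 1.6 ± 0.24), which bind zinc, and Cd14 (log2 2.17 ± 0.34), a receptor for bacterial lipopolysaccharide, rose. The acute phase list had a camera adjusted p of 5e-10 and adjusted p = 0.14 with an estimated correlation. By the list's mean per array, RYGB replicates 1 and 2 lay at -0.165 and -0.046, near the Sham AL arrays (-0.38 to -0.096), and the other 4 RYGB arrays between 0.383 and 0.489.

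Lipid droplet and steatosis markers fell in 6 of 22 cases and rose in 0 (9 fell and 1 rose adjusted over the list alone). The droplet protein genes Cidec (log2 -2.57 ± 0.39) and Plin4 (log2 -1.84 ± 0.3) and the acyltransferase gene Mogat1 (log2 -0.99 ± 0.13) fell. Without Sham AL replicate 4, Cidec measured log2 -2.25 and Plin4 log2 -1.73, and the list median moved from log2 -0.46 to -0.25. The camera adjusted p was 1.1e-08, 1.7e-06 without that array, and adjusted p = 0.14 with an estimated correlation over all arrays. The adipocyte list, which also holds Cidec, had a median of log2 -0.85, and -0.25 without that array. Cidec was the 1 of its 11 measured members that fell (also 1 adjusted over the list alone), its camera adjusted p was 1.8e-05, and it had adjusted p = 0.32 with an estimated correlation. Of 23 fatty acid synthesis genes, 2 fell and 0 rose (7 fell adjusted over the list alone), with a median of log2 -0.35, and -0.34 without that array. The camera adjusted p of this list was 1.1e-08, and adjusted p = 0.14 with an estimated correlation. Its member Fasn, the fatty acid synthase, measured log2 -0.93 ± 0.28 (adjusted p = 0.13) and was not called.

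Of 25 xenobiotic metabolism genes, 4 fell and 0 rose (7 fell and 2 rose adjusted over the list alone), among them Cyp3a11 (log2 -1.39 ± 0.2) and Cyp2c37 (log2 -0.97 ± 0.2). The camera adjusted p was 0.00034, and adjusted p = 0.14 with an estimated correlation. Male-predominant liver genes fell in 4 of 20 cases (9 fell and 1 rose adjusted over the list alone; camera adjusted p = 1.6e-07, adjusted p = 0.32 with an estimated correlation). By the mean of the list per array, relative to all arrays, RYGB replicates 1 and 2 lay at 0.713 and 0.424, above and within the range of the Sham AL arrays (0.248 to 0.628), and RYGB replicates 3 to 6 between -1.099 and -0.625. The steepest of these falls was that of Elovl3, an elongase of very long fatty acids, at log2 -2.79 ± 0.67 (adjusted p = 0.046). Leaving out RYGB replicate 3, 4, 5 or 6, BWm replicate 1 or 4 or any Sham AL replicate ended this call, with an adjusted p of up to 0.12. Of 21 genes of insulin, growth hormone and IGF signalling, 4 rose and 0 fell (7 rose and 1 fell adjusted over the list alone), among them Igfbp1 (log2 1.59 ± 0.27) and Igfbp2 (log2 1.1 ± 0.18), which bind IGF in plasma, and Trib3. The camera adjusted p was 0.0038, and adjusted p = 0.15 with an estimated correlation. The median of this list was log2 0.07, and -0.01 without Sham AL replicate 4 (camera adjusted p = 0.048). The list mixes receptors, signalling proteins and proteins that bind IGF, so here and below its direction does not give that of signalling.

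Fatty acid oxidation genes went both ways, with 2 of 32 rising and 3 falling (4 and 8 adjusted over the list alone). Fgf21, a hormone of the fasted liver, rose 2.86-fold (log2 1.51 ± 0.23) and Cyp4a31, a fatty acid hydroxylase, rose by log2 2.02 ± 0.33, whereas Acaa1b, a peroxisomal thiolase, fell by log2 1.3 ± 0.18. The list's median was log2 -0.15 and its mean 0, and camera called it lower (adjusted p = 0.032, adjusted p = 0.43 with an estimated correlation). That call ended without RYGB replicate 5 or 6 or Sham AL replicate 1, 3 or 5, with an adjusted p of up to 0.088. The genes of bile acid synthesis fixed in advance did not pass the test, with Cyp7a1, the rate-limiting enzyme, at log2 0.08 ± 0.31 (adjusted p = 0.95) and Cyp8b1 at -0.3 ± 0.35 (adjusted p = 0.79). Nr0b2, the bile acid-induced repressor, was at log2 0.06 ± 0.26 and the bile salt pump gene Abcb11 at 0.12 ± 0.14. Among the other fixed genes that were not called, Srebf1 measured log2 -1.14 ± 0.37, G6pc -0.77 ± 0.37, Apoa4 -0.47 ± 0.25, Cd36 -0.26 ± 0.17, Cyp2b10 -0.22 ± 0.18, Cpt1a 0.18 ± 0.09 and Pck1 0.09 ± 0.11. Cyp39a1, an oxysterol hydroxylase of bile acid synthesis, rose by log2 1.95 ± 0.29 and was the 1 called gene of the 16 on the bile acid synthesis list (camera adjusted p = 0.33, and 0.067 without Sham AL replicate 4).

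Camera called some marker lists of other liver cells in the same comparison, none of them with an estimated correlation. The Kupffer cell list, markers of resident macrophages, had a median of log2 0.36 (1 of 17 rose, 7 adjusted over the list alone; camera adjusted p = 5.3e-07, adjusted p = 0.25 with an estimated correlation). Its 1 called gene, Adgre1, was not called without RYGB replicate 2 or 4 or Sham AL replicate 1, 2, 4 or 5, with an adjusted p of up to 0.094. Neutrophil markers had a median of log2 0.34 with 0 of 16 called over all genes and 2 over the list alone (camera adjusted p = 2.8e-05, adjusted p = 0.32 with an estimated correlation). Cell cycle genes had a median of log2 0.24 with 0 of 28 called either way (camera adjusted p = 9.4e-05, adjusted p = 0.45 with an estimated correlation), and by the list's mean 2 of 6 RYGB arrays lay above all Sham AL arrays. For neutrophil, recruited macrophage and inflammatory genes it was 3 of 6, for Kupffer cell genes 4 of 6 and for respiratory chain genes, lower as a list, 0 of 6 lay below all Sham AL arrays. The hepatocyte list had a median of log2 -0.01 (camera adjusted p = 0.73). Weaker camera calls were made for recruited macrophages, higher (0 of 18 called either way, adjusted p = 0.018, adjusted p = 0.55 with an estimated correlation), and inflammatory signalling, higher (1 of 26 rose, 1 also over the list alone, adjusted p = 0.029, adjusted p = 0.45 with an estimated correlation). Gluconeogenesis was called lower (1 of 19 fell, 2 over the list alone, adjusted p = 0.044, adjusted p = 0.36 with an estimated correlation). The respiratory chain list was called lower at adjusted p = 0.03 (1 of 34 fell, 1 also over the list alone, adjusted p = 0.63 with an estimated correlation), and its adjusted p was 0.52 without Sham AL replicate 4. The macrophage call ended without RYGB replicate 4 or 5 or Sham AL replicate 1 or 2 (adjusted p of up to 0.25), and the inflammatory call without RYGB replicate 2, 4 or 5 or Sham AL replicate 1 or 4 (up to 0.15, and 0.093 without Sham AL replicate 4). The gluconeogenesis call ended without RYGB replicate 5 or 6, Sham AL replicate 1 or 3 or BWm replicate 4 (up to 0.26), and the respiratory chain call also without RYGB replicate 1, 5 or 6.

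In all, 306 of 22180 genes passed an adjusted p of 0.05 in RYGB against Sham AL, 208 higher and 98 lower, and 213 of them changed at least 1.5-fold. For all 42 called genes among the 74 named by rule, all 6 RYGB arrays lay on the side of the call from the Sham AL mean. The calls were made on the same arrays, which largely fixes this count. For 35 of the 42, all 6 RYGB arrays lay beyond all Sham AL arrays. Camera called 19 of 38 lists, 11 higher and 8 lower, of which 0 were called with an estimated correlation and 9 were called by fry. The count of genes was 144 without Sham AL replicate 2, 176 without RYGB replicate 4 and 200 without RYGB replicate 6, and 14 of the 42 named calls ended in at least 1 such fit. Without Sham AL replicate 4, 10 ATF4 targets, 3 ER folding, 5 cholesterol synthesis, 4 acute phase and 0 Kupffer cell genes rose, and 3 male-predominant and 5 xenobiotic metabolism genes fell. The lists of bile acid and biliary lipid transport (median log2 -0.12, camera adjusted p = 0.16) and sinusoidal endothelial cells (median log2 -0.1, camera adjusted p = 0.13) were not called over all arrays. Without that array they were called lower (medians of log2 -0.19 and -0.1, camera adjusted p = 0.029 and 0.035). Over all arrays, the endothelial list had a camera adjusted p of 0.00079 with the block for animal number and of 0.94 with the replicate block. By the list means, all 6 RYGB arrays lay beyond all Sham AL arrays in 4 of the 19 lists called.

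**Figure D2:**
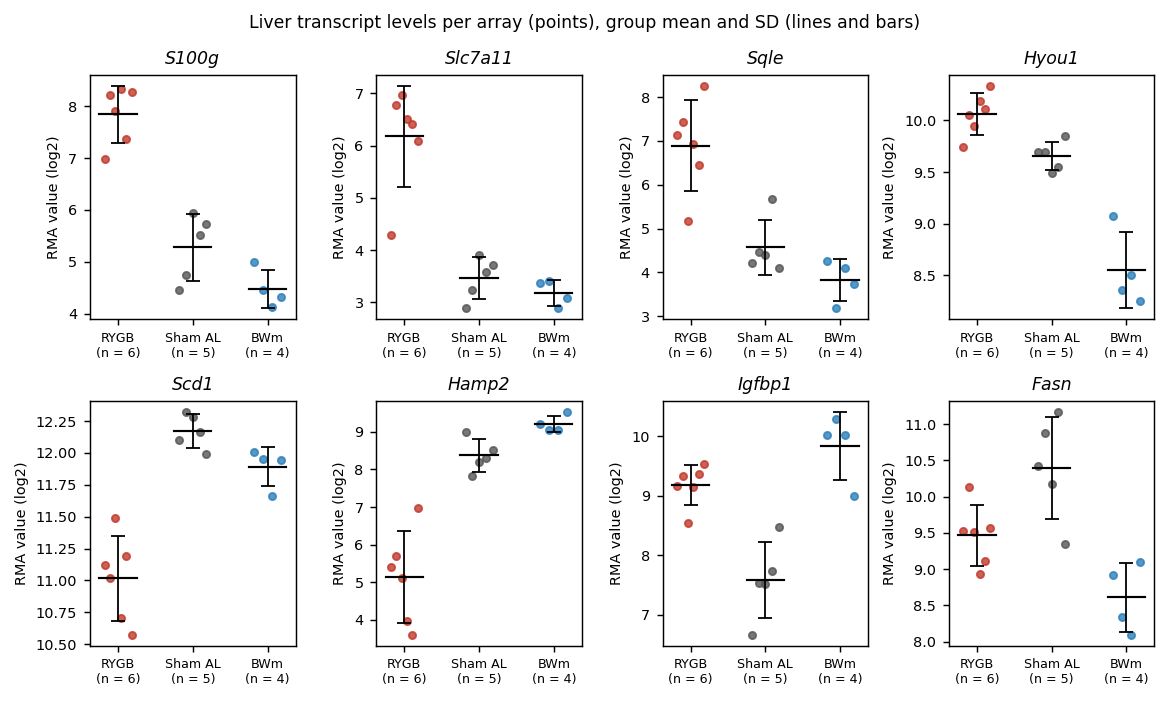
Log2 signal (y axes) of 8 genes on each array, by group on the x axis (RYGB n = 6, Sham AL n = 5, BWm n = 4), with points for single arrays, lines for group means and bars for the SD. Slc7a11 averages 6.18 in RYGB, 3.47 in Sham AL and 3.18 in BWm, and Igfbp1 averages 9.18, 7.59 and 9.83.

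The comparison of RYGB with BWm asks what bypass changed at a matched body weight. ER folding (17 of 20 called) and cholesterol synthesis genes (13 of 20 called) were higher after bypass as lists, and fatty acid oxidation genes (11 of 32 lower, 1 higher) were lower. With an estimated correlation these had adjusted p = 0.028, 0.12 and 0.028. Sprr1a, a cornified envelope protein induced in stressed epithelia, rose 20.7-fold (log2 4.37 ± 0.41 SE, adjusted p = 1.6e-05), from 3.67 ± 0.83 (SD, n = 4) to 8.04 ± 0.81 (SD, n = 6). Its BWm mean lay under the lowest array median of 3.89, and signal over background was not measured, so the exact fold is uncertain. S100g rose 10.4-fold (log2 3.38 ± 0.3 SE, adjusted p = 1.3e-05) and Sqle 8.4-fold (log2 3.07 ± 0.43 SE, adjusted p = 0.00028). Hamp2 fell 17-fold (log2 -4.09 ± 0.45 SE, adjusted p = 4.5e-05) and Acot1, an acyl-CoA thioesterase, fell 5.18-fold (log2 -2.37 ± 0.34 SE, adjusted p = 0.00034). Acot1 was called higher in BWm against Sham AL, so its difference here need not be a fall after bypass.

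Of 20 ER folding genes, 17 rose and 0 fell (18 rose adjusted over the list alone), with a median of log2 0.78. The chaperone gene Hyou1 rose by log2 1.51 ± 0.15, Sdf2l1 by 1.82 ± 0.17 and Manf, a secreted stress factor, by 1.39 ± 0.14. The list passed with the preset correlation (camera adjusted p = 3.1e-28) and with an estimated one (adjusted p = 0.028). ATF4 targets rose in 13 of 22 cases (17 rose and 1 fell adjusted over the list alone), with Nupr1 at log2 2.41 ± 0.31 and Atf3 at 1.99 ± 0.25. NRF2 targets rose in 9 of 18 (10 adjusted over the list alone), with Srxn1, which repairs peroxiredoxins, at log2 2.38 ± 0.21. Both lists, which share Slc7a11, also passed with an estimated correlation (adjusted p = 0.028 for each), beside camera adjusted p values of 1.7e-11 and 1.1e-11. Cholesterol synthesis genes rose in 13 of 20 cases (15 adjusted over the list alone), with Cyp51 at log2 2.21 ± 0.31 and Nsdhl at 1.91 ± 0.28 (camera adjusted p = 6e-13, adjusted p = 0.12 with an estimated correlation).

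Fatty acid oxidation genes fell in 11 of 32 cases and rose in 1 (15 and 2 adjusted over the list alone). Beside Acot1, Angptl4, an inhibitor of lipoprotein lipase, fell by log2 1.08 ± 0.16 and Acaa1b by log2 1.13 ± 0.19, whereas the rise was that of Fgf21 (log2 1.36 ± 0.25). This list passed with both correlations (camera adjusted p = 1.1e-11, adjusted p = 0.028 with an estimated correlation). In RYGB against Sham AL its median was log2 -0.15 and its mean 0, and in BWm against Sham AL it was called higher. Insulin, growth hormone and IGF genes fell in 5 of 21 cases and rose in 1 (13 and 2 adjusted over the list alone). The insulin receptor substrate Irs2 fell by log2 1.25 ± 0.21 and the transcription factor Foxo1 by log2 0.81 ± 0.12, and Trib3 rose by log2 1.62 ± 0.24. This list too passed with both (camera adjusted p = 3e-06, adjusted p = 0.028 with an estimated correlation). Genes of amino acid breakdown and the urea cycle fell in 5 of 32 cases (8 fell and 1 rose adjusted over the list alone), with Aass at log2 -0.71 ± 0.12 (camera adjusted p = 1.1e-06, adjusted p = 0.19 with an estimated correlation). That list was not called in RYGB against Sham AL (median log2 -0.02, camera adjusted p = 0.98), and it was called higher in BWm against Sham AL. Gluconeogenesis genes fell in 6 of 19 cases (7 fell and 2 rose adjusted over the list alone), with G6pc, the glucose-6-phosphatase, at log2 -1.7 ± 0.39 (camera adjusted p = 0.002, adjusted p = 0.16 with an estimated correlation). Pck1 fell by log2 0.5 ± 0.12 (adjusted p = 0.012), and its adjusted p was 0.053 without BWm replicate 1.

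Interferon response genes rose in 9 of 26 cases (10 adjusted over the list alone), with Usp18 at log2 1.16 ± 0.14 and Isg15 at 1.15 ± 0.16 (camera adjusted p = 1.1e-09, adjusted p = 0.081 with an estimated correlation). In RYGB against Sham AL the interferon list was not called (1 of 26 rose, median log2 0.01, camera adjusted p = 0.86). It was called lower in BWm against Sham AL. Cell cycle genes rose in 7 of 28 cases (10 adjusted over the list alone), with the replication helicase genes Mcm6 at log2 1.47 ± 0.22 and Mcm2 at 1.03 ± 0.14 (camera adjusted p = 1.5e-11, adjusted p = 0.18 with an estimated correlation). By the list's mean, RYGB replicates 2 and 5 lay at 0.607 and 0.8 and the other 4 between -0.058 and 0.077, against -0.508 to -0.16 in BWm and -0.099 to 0.155 in Sham AL. Xenobiotic metabolism genes fell in 7 and rose in 3 of 25 cases (12 and 4 adjusted over the list alone), with Cyp2c37 at log2 -1.34 ± 0.21 and Gstm3, a glutathione transferase, at 1.67 ± 0.3 (camera adjusted p = 0.00017, adjusted p = 0.072 with an estimated correlation). Bile acid and biliary lipid transport genes fell in 5 and rose in 1 of 15 cases (6 and 1 adjusted over the list alone), the rise being that of Abcc4, an exporter of bile acids to blood, at log2 2.07 ± 0.3. The camera adjusted p of this list was 0.039 (adjusted p = 0.28 with an estimated correlation), and its call ended without RYGB replicate 4, 5 or 6 or BWm replicate 1, 3 or 4 (adjusted p of up to 0.076). The bile acid synthesis list had a median of log2 -0.18 with 2 of 16 lower and 1 higher (3 and 1 adjusted over the list alone; camera adjusted p = 0.03, adjusted p = 0.4 with an estimated correlation), and its call ended without RYGB replicate 5 or 6 or BWm replicate 1, 3 or 4 (adjusted p of up to 0.08). Cyp7a1 measured log2 0.11 ± 0.33 (adjusted p = 0.92) and Cyp8b1 -0.75 ± 0.38 (adjusted p = 0.31).

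Of the other fixed genes, Scd1 fell by log2 0.88 ± 0.15 (adjusted p = 0.0013), and Cyp2b10 fell by log2 0.7 ± 0.2 (adjusted p = 0.037) but was not called without BWm replicate 1, 2 or 3 or any RYGB replicate other than 3, with an adjusted p of up to 0.16. Those not called were Fasn (log2 0.85 ± 0.3), Igfbp1 (-0.65 ± 0.28), Cd36 (0.36 ± 0.18), Abcb11 (0.2 ± 0.15), Srebf1 (0.2 ± 0.4), Cpt1a (-0.14 ± 0.1), Apoa4 (-0.1 ± 0.27) and Nr0b2 (-0.07 ± 0.28). The lipid droplet list (median log2 -0.1, camera adjusted p = 0.21) and the fatty acid synthesis list (median log2 0.04, mean -0.07, camera adjusted p = 0.33) were not called.

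Camera called marker lists of other cells here too, again none of them with an estimated correlation. Recruited macrophage markers had a median of log2 0.47, with 4 of 18 higher (9 adjusted over the list alone; camera adjusted p = 4.6e-07, adjusted p = 0.19 with an estimated correlation), among them Mmp12 (log2 1.61 ± 0.29) and Lgals3 (log2 1.02 ± 0.16), which the extracellular matrix list also holds. Sinusoidal endothelial markers fell in 4 of 19 cases (9 adjusted over the list alone; median log2 -0.38, camera adjusted p = 3.4e-06, adjusted p = 0.2 with an estimated correlation). Neutrophil markers had a median of log2 0.41 with 1 of 16 higher (7 adjusted over the list alone, camera adjusted p = 0.00015, adjusted p = 0.27 with an estimated correlation). The 1 higher gene was Lcn2, the neutrophil gelatinase-associated lipocalin, which hepatocytes also make, at log2 1.52 ± 0.34. The hepatocyte list had a median of log2 -0.11 with 0 of 18 called either way (camera adjusted p = 0.0077, adjusted p = 0.26 with an estimated correlation). The Kupffer cell list had a median of log2 0.21 with 1 of 17 higher (5 adjusted over the list alone; camera adjusted p = 0.0096, adjusted p = 0.43 with an estimated correlation), and its call ended without BWm replicate 3 or 4 (adjusted p of up to 0.13). Camera also called inflammatory signalling (4 of 26 higher, 10 over the list alone, adjusted p = 0.16 with an estimated correlation), extracellular matrix (4 of 26 higher, 6 over the list alone, adjusted p = 0.27 with an estimated correlation) and acute phase genes (6 of 31 higher and 1 lower, 7 and 1 over the list alone, adjusted p = 0.4 with an estimated correlation) higher. It called respiratory chain (1 of 34 lower, 0 over the list alone, adjusted p = 0.28 with an estimated correlation) and female-predominant genes (4 of 24 lower, 4 also over the list alone, adjusted p = 0.22 with an estimated correlation) lower. Weaker calls were made for lipoprotein genes, lower (1 of 20 fell, 1 also over the list alone; camera adjusted p = 0.011, adjusted p = 0.22 with an estimated correlation), and MHC class II genes, higher (0 of 10 called either way; camera adjusted p = 0.029, adjusted p = 0.4 with an estimated correlation). The first ended without BWm replicate 2 (adjusted p = 0.067), and the second without RYGB replicate 2, 4 or 5 or BWm replicate 4 (up to 0.072).

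In RYGB against BWm 1411 genes passed, 892 higher and 519 lower, and 769 of them changed at least 1.5-fold. For 71 of the 72 called genes named by rule, all 6 RYGB arrays lay on the side of the call from the BWm mean. The exception was Bmp2, a signal of endothelial cells, at log2 -0.53 ± 0.15. The calls were made on the same arrays, which largely fixes the count of 71. For 60 of the 72, all 6 RYGB arrays lay beyond all BWm arrays. Camera called 25 lists, 13 higher and 12 lower, of which 5 were called with an estimated correlation and 19 by fry. By the list means, all 6 RYGB arrays lay beyond all BWm arrays in 12 of the 25 lists. The count of genes was 930 without BWm replicate 3, and 15 of the 72 named calls ended in at least 1 fit without 1 array, that of Bmp2 without any 1 BWm replicate or RYGB replicate 3, 4, 5 or 6 (adjusted p of up to 0.097).

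**Figure D3:**
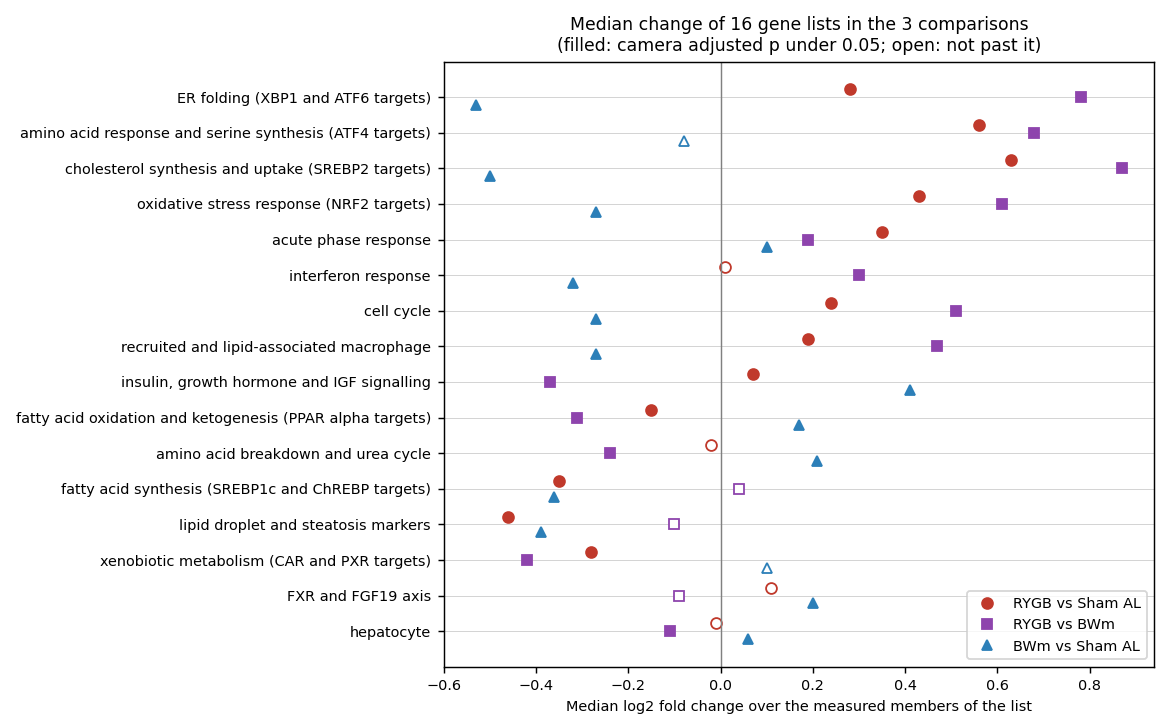
Median log2 fold change (x axis) over the measured members of 16 gene lists (y axis) in RYGB against Sham AL (circles), RYGB against BWm (squares) and BWm against Sham AL (triangles), filled where the camera adjusted p with the preset correlation was under 0.05. The ER folding list lies at 0.28, 0.78 and -0.53 in these comparisons.

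The comparison of BWm with Sham AL asks what weight loss without bypass changed. As lists, genes of insulin, growth hormone and IGF signalling (7 of 21 called) and fatty acid oxidation genes (7 of 32) were higher in the weight-matched mice, and ER folding (10 of 20), interferon response (8 of 26) and fatty acid synthesis genes (4 of 23) were lower. With an estimated correlation these had adjusted p = 0.0045, 0.1, 0.1, 0.1 and 0.39, in this order. Lepr, the leptin receptor, rose 5.89-fold (log2 2.56 ± 0.3 SE, adjusted p = 0.00066), from 4.45 ± 0.55 (SD, n = 5) to 7.01 ± 0.42 (SD, n = 4). Acot1 rose 5.44-fold (log2 2.44 ± 0.35 SE, adjusted p = 0.0016) and Igfbp1 4.74-fold (log2 2.24 ± 0.3 SE, adjusted p = 0.00091). Fasn fell 3.45-fold (log2 -1.79 ± 0.31 SE, adjusted p = 0.0037). Aqp8, a water and peroxide channel, fell 3.76-fold (log2 -1.91 ± 0.19 SE, adjusted p = 0.00019).

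Of 21 insulin, growth hormone and IGF genes, 7 rose and 0 fell (12 rose adjusted over the list alone). Beside Lepr and Igfbp1, Irs2 rose by log2 1.73 ± 0.22. These are transcripts of genes with different roles, and whether signalling itself was higher or lower was not measured. This list was called with both correlations (camera adjusted p = 5.5e-12, adjusted p = 0.0045 with an estimated correlation). Fatty acid oxidation genes rose in 7 of 32 cases and fell in 0 (11 and 1 adjusted over the list alone), with Acot3 at log2 2.1 ± 0.32 and Acot4 at 1.34 ± 0.22 (camera adjusted p = 1.3e-07, adjusted p = 0.1 with an estimated correlation). Amino acid breakdown and urea cycle genes rose in 5 of 32 cases (8 adjusted over the list alone), with the aspartate aminotransferase gene Got1 at log2 1.22 ± 0.24 and the urea cycle gene Asl at 0.94 ± 0.15 (camera adjusted p = 3.8e-07, adjusted p = 0.29 with an estimated correlation). Female-predominant liver genes rose in 4 of 24 cases (8 adjusted over the list alone; camera adjusted p = 3.8e-05, adjusted p = 0.19 with an estimated correlation). Its called members Cyp4a14, a fatty acid hydroxylase (log2 1.99 ± 0.38), and Acot3 are also known as PPAR alpha targets, and Fmo2, a flavin monooxygenase, measured log2 2.02 ± 0.27. Pck1 rose by log2 0.59 ± 0.12 (adjusted p = 0.012). Acute phase genes rose in 3 and fell in 1 of 31 cases (7 and 3 adjusted over the list alone), Mt1 and Mt2 among the rises, with a camera adjusted p of 0.035 (adjusted p = 0.54 with an estimated correlation). That call ended without Sham AL replicate 4 (adjusted p = 0.18), RYGB replicate 1, Sham AL replicate 1 or BWm replicate 2 (up to 0.23).

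ER folding genes fell in 10 of 20 cases and rose in 0 (14 fell adjusted over the list alone), with Hyou1 at log2 -1.11 ± 0.15 and Sdf2l1 at -1.08 ± 0.18 (camera adjusted p = 4.7e-16, adjusted p = 0.1 with an estimated correlation). Interferon response genes fell in 8 of 26 cases (11 adjusted over the list alone), with Isg15 at log2 -0.89 ± 0.16 (camera adjusted p = 2.1e-10, adjusted p = 0.1 with an estimated correlation). Fatty acid synthesis genes fell in 4 of 23 cases (8 adjusted over the list alone), with Mid1ip1, an activator of acetyl-CoA carboxylase, at log2 -0.85 ± 0.16 beside Fasn. The median of this list was log2 -0.36, and -0.28 without Sham AL replicate 4, where Fasn measured log2 -1.59 and 3 members fell (camera adjusted p = 0.00068, adjusted p = 0.39 with an estimated correlation).

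Lipid droplet markers fell in 4 of 22 cases (8 fell and 2 rose adjusted over the list alone), with Cidec at log2 -2.35 ± 0.43, Mogat1 at -0.82 ± 0.14 and the adipogenic factor Pparg at -1.39 ± 0.19. Without Sham AL replicate 4 these measured log2 -2.03, -0.79 and -1.32, and the list median moved from log2 -0.39 to -0.23 (camera adjusted p = 0.00067, 0.0028 without that array, and adjusted p = 0.39 with an estimated correlation). The adipocyte list had a median of log2 -0.85 and of -0.15 without that array, where its camera adjusted p was 0.22 in place of 0.0095 (adjusted p = 0.48 with an estimated correlation). Of its 11 members, Cidec fell and Pck1, which hepatocytes also express, rose (the same numbers adjusted over the list alone, 1 and 1). The cholesterol synthesis list had a median of log2 -0.5, and -0.44 without that array, with 0 of 20 genes called over all genes and 4 lower over the list alone (camera adjusted p = 0.0017, adjusted p = 0.48 with an estimated correlation). The respiratory chain list had a median of log2 0.09, and 0.13 without that array, with 0 of 34 called (camera adjusted p = 0.018, 0.00027 without that array, and adjusted p = 0.54 with an estimated correlation). Its call ended without Sham AL replicate 1, 2 or 3 or BWm replicate 1 (adjusted p of up to 0.2).

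Cell cycle genes fell in 4 of 28 cases (6 adjusted over the list alone; camera adjusted p = 5e-05, adjusted p = 0.39 with an estimated correlation), with 0 called without Sham AL replicate 4. Extracellular matrix genes fell in 2 of 26 cases (9 adjusted over the list alone; camera adjusted p = 3.1e-05, adjusted p = 0.38 with an estimated correlation), among them the collagen gene Col5a3 (log2 -0.49 ± 0.1), and in 1 case without Sham AL replicate 4. Recruited macrophage markers had a median of log2 -0.27 with 2 of 18 lower (4 adjusted over the list alone; camera adjusted p = 0.00068, adjusted p = 0.39 with an estimated correlation), with 1 lower without that array. Sinusoidal endothelial markers had a median of log2 0.22, and 0.12 without that array, with 1 of 19 higher (1 also over the list alone; camera adjusted p = 0.0006, adjusted p = 0.39 with an estimated correlation). The hepatocyte list had a median of log2 0.06 with 1 of 18 higher (4 adjusted over the list alone; camera adjusted p = 0.0024, adjusted p = 0.35 with an estimated correlation). NRF2 targets were called lower (3 of 18 fell, 5 lower and 1 higher over the list alone; camera adjusted p = 0.0056, adjusted p = 0.39 with an estimated correlation). With 0 members called over all genes, camera also called male-predominant (1 lower over the list alone, adjusted p = 0.0035, adjusted p = 0.48 with an estimated correlation), MHC class II (0 over the list alone, adjusted p = 0.0056, adjusted p = 0.39 with an estimated correlation) and inflammatory signalling genes (0 over the list alone, adjusted p = 0.0095, adjusted p = 0.39 with an estimated correlation) lower. The first of these calls ended without BWm replicate 2 (adjusted p = 0.13), and the other 2 without Sham AL replicate 3 (up to 0.066). The FXR and FGF19 axis, receptors and partners that sense bile acids, had a median of log2 0.2 with 1 of 10 higher (1 also over the list alone, 0 over all genes without Sham AL replicate 4; camera adjusted p = 0.0073, adjusted p = 0.2 with an estimated correlation). The member called was Klb, the co-receptor of FGF19 and FGF21, at log2 0.73 ± 0.17 (adjusted p = 0.027, and up to 0.088 without Sham AL replicate 2 or 4 or BWm replicate 2, 3 or 4). Without Sham AL replicate 4, 4 amino acid breakdown genes, 3 female-predominant genes and 8 fatty acid oxidation genes rose, and 3 fatty acid synthesis genes fell. Cyp39a1 rose by log2 2.31 ± 0.32. Fixed genes that were not called were Srebf1 (log2 -1.34 ± 0.41), G6pc (0.94 ± 0.41), Cd36 (-0.61 ± 0.19), Cyp2b10 (0.49 ± 0.2), Cyp8b1 (0.45 ± 0.39), Apoa4 (-0.37 ± 0.28), Cpt1a (0.32 ± 0.1), Scd1 (-0.28 ± 0.15), Fgf21 (0.15 ± 0.26), Nr0b2 (0.13 ± 0.29), Abcb11 (-0.08 ± 0.16) and Cyp7a1 (-0.03 ± 0.35).

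In BWm against Sham AL 629 genes passed, 340 higher and 289 lower, and 383 of them changed at least 1.5-fold. For all 46 called genes named by rule, all 4 BWm arrays lay on the side of the call from the Sham AL mean, a count that calls on the same arrays largely fix. For 45 of the 46, all 4 BWm arrays lay beyond all Sham AL arrays. Camera called 22 lists, 9 higher and 13 lower, of which 1 was called with an estimated correlation and 8 by fry. By the list means, all 4 BWm arrays lay beyond all Sham AL arrays in 11 of the 22 lists. The B and plasma cell list, not called over all arrays (median log2 -0.2, camera adjusted p = 0.071), was called lower without Sham AL replicate 4 (median log2 -0.16, camera adjusted p = 0.021). The count of genes was 284 without BWm replicate 2, also 284 without BWm replicate 3 and 382 without Sham AL replicate 2, and 12 of the 46 named calls ended in at least 1 fit without 1 array.

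Genes that changed the same way in RYGB and in BWm against Sham AL numbered 22 higher and 12 lower, where independent lists of these sizes would share 3.19 and 1.28, and 8 genes were called in opposite directions. Mt1, Mt2, Igfbp1, Igfbp2, Cyp39a1 and Lepr were higher in both, and Cidec and Mogat1 were lower in both. Both comparisons use the same 5 Sham AL arrays. Across genes, which are not independent replicates, Pearson's r between the fold changes was 0.353, whereas unchanged groups simulated against shared controls gave 0.494. The covariance was 0.0214 against 0.0118 simulated, a difference of 0.00961. Simulated arrays took 1 spread per gene for all groups and so lack the outlying signal of Sham AL replicate 4, which both comparisons share. The difference therefore need not be shared change alone. With the Sham AL arrays split between the comparisons, the mean r of 20 splits was 0.0711 (range -0.00307 to 0.149), the mean covariance was 0.00535, and a median of 9 genes (4 to 14) were called the same way in both.

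Genes that changed the same way in RYGB against Sham AL and against BWm numbered 133 higher and 40 lower, where independent lists would share 8.37 and 2.29, and this count was chosen after the data were seen. They made up 56.5% of the genes called in RYGB against Sham AL, and among them were Slc7a11, S100g, Sqle, Atf3, Trib3, Fgf21, Scd1 and Hamp2. Both comparisons use the same RYGB arrays, which gave a simulated r of 0.425 against 0.502 measured and a covariance difference of 0.0232. With the RYGB arrays split between the comparisons, a median of 45.5 genes (21 to 101) were called the same way in both. The count of 173 genes was 99 without RYGB replicate 4 and 91 without Sham AL replicate 2.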

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

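The tests of hepatocyte genes on the array of Sham AL replicate 4, of other cell types and of low animal numbers were chosen after the results they address were seen, and the splits of the arrays and the held-out adrenal and fat genes were written before.

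Random grouping of the arrays is argued against as the source of the counts of changed genes. Such splits cannot address factors that go with the groups, such as animal number, feeding or the hour of collection. Of 100 drawn splits of the RYGB and Sham AL arrays (462 possible), 1, the real one, gave as many genes (306, highest other 6). For RYGB against BWm it was 1 of 100 (1411, highest other 17, 210 possible), and for BWm against Sham AL 1 of 100 (629, highest other 19, 126 possible).

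The gap of 1 array to its nearest neighbour, as a share of the range of its group, passed Dixon's critical value in 16 of 219 sets of 1 gene in 1 group, where chance gives about 1 in 20. The highest array stood apart for Bmp2 (0.651), Col5a3 (0.655) and Mcm2 (0.679) on RYGB replicate 2, for Manf (0.852) and Nupr1 (0.86) on BWm replicate 1, for Asl (0.759) on Sham AL replicate 1 and for Sqle (0.759) on Sham AL replicate 4. The lowest array stood apart for Slc7a11 (0.667) on RYGB replicate 1, Angptl4 (0.634) on RYGB replicate 3, Pck1 (0.641) and Usp18 (0.673) on RYGB replicate 5 and Mid1ip1 (0.678) on RYGB replicate 6. It did so too for Got1 (0.786) on Sham AL replicate 3, Aqp8 (0.731) on Sham AL replicate 4, and Cyp2c37 (0.882) and Cyp8b1 (0.949) on BWm replicate 2. Over all genes, Sham AL replicate 4 stood apart by the number of genes over 1 log2 unit from the other arrays of its group (0.893) and by the lowest median correlation with other arrays (0.83). Of 17824 transcript clusters with no symbol or several, which the comparisons did not use, 25 passed an adjusted p of 0.05 in RYGB against Sham AL, 282 in RYGB against BWm and 96 in BWm against Sham AL.

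Adrenal and fat transcripts stood out on the array of Sham AL replicate 4, with Ucp1, Star, Cyp11b1 and Chga at 11.89, 10.56, 10.37 and 10.34. A sample of another tissue in place of liver is argued against, since the hepatocyte list lay at a median of -0.12 from the other 4 Sham AL arrays. Adrenal gland and fat tissue in the piece of liver may be the source, and cannot be told for certain: the held-out medians were 1.36 for adrenal medulla, 1.88 for fat and 0.54 for adrenal cortex, where over 1 was asked of each. In the cortex list 4 of 10 genes were over 1 (Cyp21a1 5.59, Cyp11b2 4.01, Mgarp 2.27, Nr5a1 2.04), whereas Mrap, Fdx1 and Hsd3b2 already measured 7.65, 7.37 and 7.57 on the other Sham AL arrays. Kidney genes had a median of 0.02, with 0 of 15 over 1, and no biological explanation was tested.

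ER folding genes were highest in RYGB and lowest in BWm, with means per array of 9.48 ± 0.14 (SD, n = 6), 9.15 ± 0.11 (SD, n = 5) in Sham AL and 8.61 ± 0.19 (SD, n = 4) in BWm. By this mean, 6 of 6 RYGB arrays lay above all BWm arrays (exact permutation p = 0.0048, the smallest these numbers allow, adjusted 0.018 over 9 tests). The list was taken up after its camera result on the same arrays was seen, which largely fixes this separation. Animals with low numbers, of which BWm holds none, are argued against as the source, since the list median in RYGB against BWm was 0.86 among the 3 RYGB and 4 BWm animals numbered above 60, against 0.78 in all. A different share of another cell type cannot be told apart from a change within hepatocytes. The ER folding median exceeded that of the cell type that rose most, recruited macrophages (0.47), by 0.31, with a 95% bootstrap interval over genes of -0.07 to 0.63. Surgery and, against Sham AL, body weight differ by design and stay open. Food intake at collection was not measured here and stays open too. The score of fasting genes minus feeding genes given below ran in the opposite order, at 0.75 in RYGB, 1.01 in Sham AL and 1.4 in BWm.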

How the results depend on the processing

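Each count was within 1.5 times its reported value under quantile normalization (280, 1408 and 640 genes for RYGB against Sham AL, RYGB against BWm and BWm against Sham AL), subtraction of array medians (366, 1385 and 576), the mean of a gene's clusters (303, 1378 and 606), the compared groups alone (243, 1368 and 431), a trended and robust prior (344, 1509 and 739), array weights (401, 1478 and 672) and a block for animal number (380, 1497 and 785). With medians subtracted, 78.1% of the RYGB against Sham AL calls were higher, against 68% as deposited. Testing genes above the median level gave 1011 genes for BWm against Sham AL (437 and 1785 for the others), and testing all transcript clusters gave 169 for RYGB against Sham AL. Benjamini-Hochberg adjustment of the methods' one-way ANOVA gave 54, 833 and 90 genes, and its unadjusted p of 0.05 with the 1.5-fold minimum gave 370, 857 and 554, which are other rules. Genes changed the same way in RYGB against both sham groups numbered 96 with all clusters, 99 with the replicate block and 28 with the adjusted ANOVA, against 173; these alternatives were chosen after the data were seen. Camera with an estimated correlation called 0, 5 and 1 lists, and fry called 9 for RYGB against Sham AL and 8 for BWm against Sham AL. The correlation of the fold changes of RYGB and BWm against Sham AL was 0.071 with the Sham AL arrays split between them and 0.08 when replicate 4 was also left out, a setting chosen after the data were seen. Except where the construction shows it (other genes tested, separate controls), the cause was not tested.

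Replicate numbers were tried as a replicate block, which gave 174, 903 and 325 genes. The numbers did not pair the arrays: deviations from group means of arrays with the same number correlated between -0.0371 and 0.129, -0.17 and 0.11, and -0.118 and 0.19 in the 3 comparisons, over 0.1 in 2 of 5, 1 of 4 and 1 of 4 pairs. Blocking therefore spent degrees of freedom, and whether that alone lowered the counts was not tested.

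Leaving out each array in turn gave 144 (without Sham AL replicate 2) to 398 genes (without RYGB replicate 1) for RYGB against Sham AL, with 176 and 200 without RYGB replicates 4 and 6. For RYGB against BWm the range was 930 (without BWm replicate 3) to 1544 (without Sham AL replicate 4), and for BWm against Sham AL 284 (without BWm replicate 2 or 3) to 646 (without BWm replicate 4), with 382 without Sham AL replicate 2. Genes changed against both sham groups numbered 91 (without Sham AL replicate 2) to 254 (without RYGB replicate 1), with 99 without RYGB replicate 4. Lists called numbered 14 to 20, 22 to 26 and 20 to 25, and the correlation of fold changes was 0.31 to 0.424. Without Sham AL replicate 4 the counts were 318, 1544 and 499 genes and 19, 25 and 21 lists. Among animals numbered above 60 alone, chosen after the data were seen, 212, 1010 and 440 genes were called, 153, 820 and 377 of them also called in all animals. Of the named genes' 1916, 2488 and 2128 values under all alternatives, 1731, 2326 and 1967 kept their side of the threshold, 165, 129 and 119 fell short of it, 20, 33 and 42 newly passed it and 0 changed sign where either value passed it. Genes not called, such as Cyp7a1 in RYGB against Sham AL (log2 -0.07 to 0.3 with single arrays left out), did change sign. Signal over background was not measured; of the genes called, 41, 139 and 50 had a mean level under the median of 4.5, where small changes are harder to see.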

Other observations

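Genes outside the rule were looked at after their values were seen. Clock genes differed between BWm and Sham AL mice. Arntl (log2 1.61 ± 0.38, adjusted p = 0.028), Cry1 (log2 1.45 ± 0.2, adjusted p = 0.0013) and Nfil3 (log2 1.09 ± 0.18, adjusted p = 0.0034) rose, and Nr1d1 (log2 -0.87 ± 0.18, adjusted p = 0.014), Dbp (log2 -0.95 ± 0.23, adjusted p = 0.034) and Bhlhe41 (log2 -0.84 ± 0.19, adjusted p = 0.021) fell. These 6 genes did not pass in RYGB against Sham AL (adjusted p from 0.71 to 0.95), with Arntl at log2 0.21 ± 0.34 and Cry1 at log2 -0.2 ± 0.18. All 6 passed in RYGB against BWm in the opposite direction, with Arntl (log2 -1.39 ± 0.37, adjusted p = 0.028), Cry1 (log2 -1.65 ± 0.2, adjusted p = 8.8e-05) and Nfil3 (log2 -0.95 ± 0.18, adjusted p = 0.0028) lower, and Nr1d1 (log2 0.82 ± 0.18, adjusted p = 0.0074), Dbp (log2 0.88 ± 0.22, adjusted p = 0.022) and Bhlhe41 (log2 0.67 ± 0.18, adjusted p = 0.033) higher after bypass. Of the 19 measured members of the fixed clock list, 3 rose and 3 fell in BWm against Sham AL (6 and 3 adjusted over the list alone), and the list was not called (camera adjusted p = 0.17). In RYGB against BWm 3 rose and 5 fell, and the list was not called either (camera adjusted p = 0.16).

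In all 3 comparisons 11 genes were called. Fkbp11 (log2 1.39 in RYGB against Sham AL, 2.38 in RYGB against BWm and -0.99 in BWm against Sham AL), Srxn1 (1.12, 2.38 and -1.27), Sdf2l1 (0.74, 1.82 and -1.08) and Sprr1a (1.98, 4.37 and -2.39) were highest after bypass and lowest in weight-matched mice. Arfgap3, Ero1b and Tmed3 had the same order. Lepr (1.47, -1.09 and 2.56), Rdh16f2 and Fam234b were highest in weight-matched mice and lowest in Sham AL mice, and Gpat4 (-0.54, -1.06 and 0.52) was lowest after bypass. In RYGB against Sham AL the call of Sprr1a ended without Sham AL replicate 2 (adjusted p = 0.052), and that of Sdf2l1 without RYGB replicate 2, 4 or 6 or Sham AL replicate 2 or 3 (up to 0.074). Fkbp11, Sdf2l1 and Ero1b encode proteins of the endoplasmic reticulum.

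Less recent food intake is a candidate explanation for the fasting-like genes changed in BWm. Held-out genes raised by fasting minus those raised by feeding were higher in BWm (1.4 ± 0.08 SD, n = 4) than in Sham AL livers (1.01 ± 0.17 SD, n = 5), by 0.38 (exact permutation p = 0.016, adjusted 0.029 over 9 tests), in 4 of 4 BWm arrays above all Sham AL arrays. The difference came from the fasting genes (median log2 0.35, 4 of 20 higher and 1 lower), as the feeding genes had a median of -0.05. The same score was lower in RYGB (0.75 ± 0.19 SD, n = 6) than in BWm livers by -0.65 (exact permutation p = 0.0048, adjusted 0.018, 6 of 6 RYGB arrays below all BWm arrays), and than in Sham AL livers by -0.26 (exact permutation p = 0.043, adjusted 0.062), so it bears on RYGB against BWm too. A different clock phase was suggested by the clock genes above and cannot be tested on them. Among the clock genes not called in BWm against Sham AL (2 with the phase of Arntl, 8 with the opposite phase), the difference of the phases was higher in BWm than in Sham AL livers by 0.39 (exact permutation p = 0.048, adjusted 0.062), which leaves it open, and it was 0.35 in RYGB against Sham AL (exact permutation p = 0.089) and -0.04 in RYGB against BWm (exact permutation p = 0.89). These values leave out the 6 genes above, which did differ between RYGB and BWm. That test was chosen after the clock genes were seen, and the adjusted p was set as its criterion after both p values were seen. The hours of feeding and of collection are not in the labels, and weight loss itself, which the design names, may give the same changes.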
